A study of Mus musculus with 15 samples.

How the data were processed

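Total RNA of mouse left ventricle was measured on 15 oligonucleotide arrays with 12488 probe sets. The deposited values are probe-set intensities on a linear scale with an arbitrary unit. The software, background correction and scaling that the authors used are not given in the sources used here. The array medians lay within a ratio of 1.26 of each other, so the arrays as deposited had been brought to a common level, and that level was kept. The table held 8722 exact zeros and no negative values, and its highest value was 7322. No array dates, scan batches or animals are given in the labels, so no batch could be tested.

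Samples were grouped by the sex and operation in their labels into female sham (n = 3), male sham (n = 6), female TAC (n = 3) and male TAC (n = 3). The 66 control probe sets were left out, which left 12422. Values were floored at 20, because the 30th percentile of all values pooled was 11.9 and the rule took the higher of the 2, and log2 was taken. The 60% of probe sets with the highest mean log2 value were tested, 7453 in all. The floor makes changes of dim genes smaller than they were, and between 42.4% and 48.4% of the probe sets of an array lay below it. Where all arrays of a group were below the floor, a fold change is given as a lower bound.

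Gene names came from the platform annotation, with symbols updated by Entrez gene number through a RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of the 12422 probe sets, 10833 had 1 symbol, 396 had several and 1193 had none, and 10817 matched the gene table. Where a gene had several tested probe sets, the one with the highest mean was used for gene lists and named genes, and others are given where they disagree. Probe sets of gene families can bind transcripts of several members.

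One linear model with a mean for each of the 4 groups was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and the groups shared an estimate of the spread. The 6 contrasts were the TAC effect averaged over the sexes, in females and in males, the difference of the effect between the sexes, and the sex difference in sham and in TAC hearts. P-values were adjusted by Benjamini-Hochberg over the tested probe sets and called at 0.05, and errors after ± are SE unless SD is stated. Named genes were, for the averaged effect, up to 12 rises and 12 falls of largest size that passed with the same sign in both sexes, and up to 4 genes of smallest p in each list. For the other contrasts they were up to 6 in each direction that passed, or the 3 of smallest p where none did. The 20 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Contrasts, gene lists, the naming rule and the settings to be varied, apart from those named below, were fixed before the data were examined.

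The method was tested on simulated data in which 200 of 7453 probe sets were changed. The noise was drawn independently for each probe set, without correlation between genes and without the floor. More probe sets were changed than were called in the real data, which eases the adjusted threshold. The shares recovered may therefore be higher than in the real comparisons. For the averaged effect it recovered 55.2%, 95.5% and 100% of changes of 0.5, 1 and 2 on the log2 scale, with 11 false calls. For the effect in females the shares were 22.4%, 74.6% and 100%, and for that in males 31.3%, 92.5% and 97.0%. For the difference between the sexes they were 4.48%, 47.8% and 97.0%, so that differences of 0.5 could hardly be seen. For the sex difference they were 25.4%, 88.1% and 98.5% in sham hearts and 14.9%, 77.6% and 100% in TAC hearts.

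Sham and TAC titles share replicate numbers 1 to 6, so pairing was checked from the correlation of same-numbered deviations from the group means. It was 0.244, 0.270 and 0.117 for the 3 female numbers and 0.0641, -0.0828 and 0.0136 for the male numbers, so only the female numbers passed the limit of 0.1. The fit fixed beforehand has no block, so a block was run as an alternative only, and the p-values of the main results do not use the pairs. With the block in both sexes, male sham 7 to 9 have no TAC partner and add nothing to the male effect. The alternatives were quantile normalization, median centring, a floor at the 10th percentile, an offset of 20 in place of the floor, no filter on dim probe sets or a stricter one, trended and robust eBayes, array weights, an additive model, fits of only the groups compared, the replicate number as a block, 1 probe set per gene, a minimum fold of 1.5 and leaving out each array. A block in females alone, and leaving out the 2 arrays least correlated with the others, were added after seeing the data. A gene or list that passed neither before nor after a change of setting was counted as keeping its result. Single values were compared by exact permutation of the operation labels within each sex, two-sided, with the arrays exchanged freely. Exchanging female arrays only within their numbers, in 672 arrangements, a check added after the results were seen, left each of the reported tests on its side of 0.05. Figures were drawn with matplotlib 3.10.9.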

Results

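Gene expression was measured in mouse left ventricle with 15 one-colour oligonucleotide arrays, in a series on cardiac hypertrophy under pressure overload. The labels name 4 groups by sex and by operation: 3 female sham hearts, 6 male sham hearts, 3 female hearts with the operation called TAC, and 3 male hearts with TAC. Sham hearts came from animals labelled as sham controls. Each array gave 12488 probe-set intensities, of which 66 were control probe sets. Array medians lay between 21.2 and 26.7 intensity units, and the number of arrays limits the precision. The labels describe each sample as a heart but do not say that each came from a separate animal, so the p-values measure only the spread between these samples.

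Sex-linked genes were read first, as a check of the labels. Xist, the non-coding RNA of X inactivation, had a mean intensity of 33.0 ± 2.9 (SD, n = 3) in female sham hearts and 29.5 ± 9.3 (SD, n = 3) in female TAC hearts. In male hearts it averaged 1.3 ± 1.5 (SD, n = 6) after sham and 2.1 ± 1.9 (SD, n = 3) after TAC, below the floor of 20 on all male arrays. The probe sets of the Y-linked genes Uty, Kdm5d and Eif2s3y had mean intensities below 20 in all 4 groups, under the floor, and were not used to tell the sexes apart.

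The main comparison asked how left ventricular expression differed between TAC and sham hearts, taken within each sex and averaged. Nppa and Acta1, both in the list of hypertrophy stress genes, rose most. Nppa, which encodes atrial natriuretic peptide, was 7.11-fold higher with TAC (95% interval 5.17 to 9.78), with a log2 change of 2.83 ± 0.22 (SE). Acta1, the skeletal muscle alpha-actin, rose 4.32-fold, with a log2 change of 2.11 ± 0.14 (SE). Ankrd1, a stress-responsive nuclear and sarcomeric protein, rose 2.14-fold, by 1.10 ± 0.11 (SE). The matrix genes Postn (periostin), Ccn2 (connective tissue growth factor), Col8a1 and Bgn (biglycan) rose by log2 changes of 1.45 ± 0.19, 1.25 ± 0.18, 1.02 ± 0.17 and 0.80 ± 0.13 (SE).

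Across the 7453 probe sets tested, limma called 24 at an adjusted p under 0.05, of which 20 were higher and 4 were lower with TAC. At an unadjusted p under 0.05 the balance was the other way, with 213 higher and 347 lower, 560 in all where 373 would be expected by chance. The median log2 change over all tested probe sets was -0.03, and whether the level of the arrays contributes to this balance was not tested. The 24 called probe sets stood for 17 genes that were higher, 4 that were lower and 2 probe sets without a single gene symbol.

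**Figure D1:**
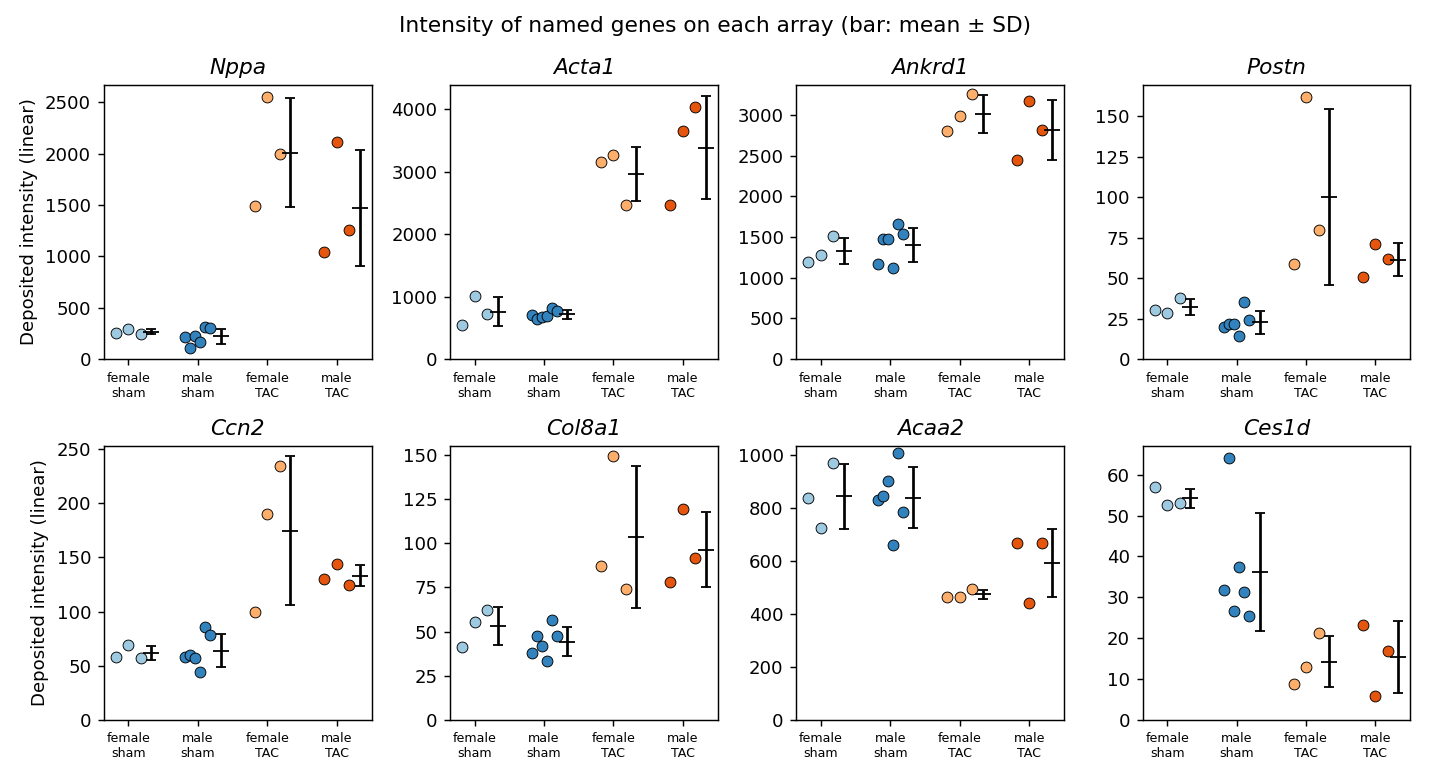
Deposited linear intensity of 8 genes on each of the 15 arrays, by group, with a bar for the mean ± SD of the group. Nppa lay between 1045 and 2549 on the 6 TAC arrays and between 111 and 307 on the 9 sham arrays, and Acaa2 and Ces1d had lower means after TAC.

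In intensity units, Nppa averaged 264 ± 25 (SD, n = 3) in female sham and 2011 ± 531 (SD, n = 3) in female TAC hearts. In males the means were 220 ± 76 (SD, n = 6) and 1473 ± 568 (SD, n = 3). Acta1 went from 757 ± 231 to 2968 ± 433 in females and from 715 ± 67 to 3383 ± 822 in males (SD, same n). The adjusted p from limma was 1.29e-06 for Nppa and 3.55e-07 for Acta1. The other large rises were those of a probe set annotated to Dohh, an enzyme of hypusine synthesis, by 1.57 ± 0.14, and of Enah, an actin regulator, by 1.08 ± 0.22. The name Dohh rests on an EST in the platform annotation and was not checked by sequence. Gpx3, an extracellular glutathione peroxidase, rose by 0.84 ± 0.15 and Fhl1, a LIM-domain protein of striated muscle, by 0.83 ± 0.16. Ninj1, an adhesion protein, was below the floor on all 3 female sham arrays and on 5 of the 6 male sham arrays, so its rise was at least 1.77-fold. Several genes had a further probe set that did not pass: Bgn with 0.31 ± 0.14 (adjusted p = 0.611) and Enah with 0.45 ± 0.22 (adjusted p = 0.677). The second probe set of Fhl1 did pass in limma, with a rise of 1.33 ± 0.16 (adjusted p = 0.00024). The lost calls given for Fhl1 below are those of its brighter probe set, with 0.83. The 4 genes that fell were Ces1d, a carboxylesterase, by 1.06 ± 0.16 on the log2 scale, Acaa2, the last enzyme of mitochondrial beta-oxidation, by 0.67 ± 0.12, Pik3ca by 0.59 ± 0.12 and Ech1, an isomerase of beta-oxidation, by 0.56 ± 0.11. Ces1d was below the floor on 4 of the 6 TAC arrays, which limits how far its fall could be measured. Nppa, Acta1, Ankrd1, Postn and Ccn2 kept their calls under each alternative and without any single array. Of the 15 runs without 1 array, Pik3ca and Ech1 each lost the call in 13 (adjusted p up to 0.189 and 0.194), Enah and Fhl1 in 12 (up to 0.194 and 0.166), Ninj1 in 10, Gpx3 in 5 (up to 0.104 for both) and Acaa2 in 4 (up to 0.0807). Pik3ca and Ech1 also lost it with the replicate number as a block in females alone (adjusted p = 0.0575 and 0.0502). Enah, Fhl1, Gpx3, Ninj1, Acaa2, Pik3ca and Ech1 lost their calls without the filter on dim probe sets (adjusted p from 0.0893 to 0.204), with a lower floor (0.0518 to 0.184) and with the block in both sexes (0.0558 to 0.328), and in all Pik3ca lost its call in 7 of 12 alternatives, Ech1 in 6 of 13 and Fhl1 in 4 of 13. Col8a1 and Ces1d lost theirs without the filter (adjusted p = 0.0893 and 0.0752) and with the block in both sexes (0.0585 and 0.0591), Bgn with that block (0.0591) and Dohh with the lower floor (0.0536). The lower floor also moved the log2 change of Ces1d to -1.70 and that of Ninj1 to 1.53, and the offset moved that of Pik3ca to -0.38.

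The hypertrophy stress list held 15 tested genes, of which 13 were higher and 2 lower with TAC. In this list 5 genes were called over all probe sets and 8 when adjusted over the list alone, with a median log2 change of 0.69. The camera test with a preset correlation called the list higher (adjusted p = 6.89e-17), and the call held with an estimated correlation (adjusted p = 0.0190). Of the 37 tested genes of the extracellular matrix list, 29 were higher, 4 were called and 9 were called when adjusted over the list alone. The list was called higher with a median of 0.21 (adjusted p = 4.27e-14), which was lost with an estimated correlation (adjusted p = 0.0711) but not with fry (adjusted p = 0.0348). Markers of fibroblasts, the main matrix-producing cells, had a median of 0.07 and were not called (adjusted p = 0.187).

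In the fatty acid oxidation list 22 of 25 tested genes were lower, with a median of -0.25. Acaa2 alone was called over all probe sets, and 7 genes were called when adjusted over the list alone, among them Eci1 with -0.63 ± 0.14, which was called over all probe sets in 5 of 13 alternatives, and Echs1 with -0.49 ± 0.13, called in 1 of 13. In the oxidative phosphorylation list 55 of 59 genes were lower with a median of -0.18, and in the tricarboxylic acid cycle list 15 of 16 were lower with a median of -0.22. Neither list had a called gene, over all probe sets or over the list alone. The preset camera test called the 3 lists lower, with adjusted p of 1.93e-08, 8.27e-10 and 0.000139. None of these calls held with an estimated correlation, where the adjusted p was 0.220, 0.357 and 0.357, and the last 2 were lost with fry as well (adjusted p = 0.143 and 0.192). Glycolysis and glucose uptake genes were not called (adjusted p = 0.955). Their median was 0.05 and their mean -0.02, and Eno3, the muscle enolase, had -0.43 ± 0.09 (adjusted p = 0.0534) and was called in 7 of 13 alternatives.

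Calcium handling and ion channel genes were lower in 10 of 13 cases, with a median of -0.16. None was called over all probe sets and 3 were when adjusted over the list alone: Ryr2, the calcium release channel of the sarcoplasmic reticulum, with -0.52 ± 0.13, Hrc with -0.29 ± 0.08 and Kcnq1 with -0.31 ± 0.10. Of 13 alternatives, 2 called Ryr2 over all probe sets and 1 called Hrc. The list was called lower (adjusted p = 0.00364) and lost that call with an estimated correlation (adjusted p = 0.220) but not with fry (adjusted p = 0.0417). Antioxidant genes were called higher (adjusted p = 0.0147), but not with an estimated correlation (adjusted p = 0.357), with fry (adjusted p = 0.376), or without female sham 1 or female TAC 2 (adjusted p = 0.0615 and 0.0806). Their median was 0.06, and Gpx3 was the called member among 19. Atrial markers were called higher (adjusted p = 0.00936) through Nppa, since their median was -0.02 and their mean 0.80, but not with an estimated correlation (adjusted p = 0.357) or without male TAC 5 (adjusted p = 0.0667). With fry the atrial markers stayed called (adjusted p = 0.0417). Myl7 and Myl4, the other members and light chains abundant in atria, had -0.02 ± 0.32 and -0.41 ± 0.41.

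The remaining lists were not called in the averaged comparison. Endothelial markers had a median of 0.03 (adjusted p = 0.243), macrophage and leukocyte markers -0.01 (adjusted p = 0.656) and smooth muscle markers -0.18 (adjusted p = 0.154). Chaperones had a median of 0.01 (adjusted p = 0.154), skeletal muscle markers -0.13 (adjusted p = 0.193) and sex chromosome genes -0.10 (adjusted p = 0.277). Without male sham 5 the chaperones were called higher by camera at the preset correlation (adjusted p = 0.0278). Immediate early genes had an adjusted p of 0.707, and cell cycle genes, red blood cell markers and fat cell markers had 0.904 each.

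**Figure D2:**
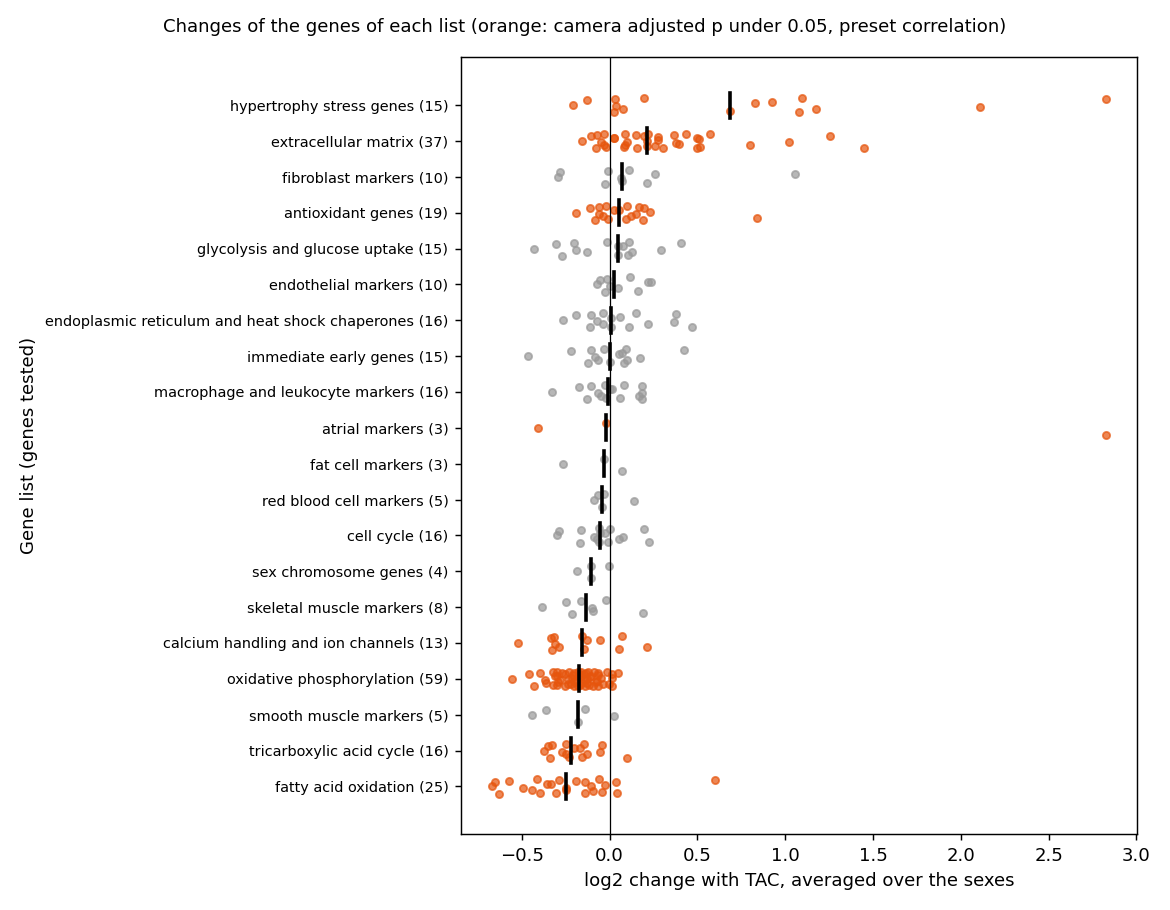
Log2 change with TAC, averaged over the sexes, of each tested gene (points) in the 20 gene lists, with the list median as a black bar and the number of genes tested in brackets. Orange lists had a camera adjusted p under 0.05 with the preset correlation. The medians ran from 0.69 for hypertrophy stress genes to -0.25 for fatty acid oxidation genes.

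The number of calls depended on single arrays and on the processing. Leaving out 1 array at a time gave 12 to 29 calls, with the lowest count without male TAC 5, and centring each array on its median or normalizing quantiles gave 45. Male TAC 6 moved the balance, since 16 higher and 13 lower probe sets were called without it.

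The effect of TAC in females compared 3 TAC with 3 sham hearts. Nppa rose by 2.90 ± 0.33, Acta1 by 2.00 ± 0.22, Dohh by 1.54 ± 0.22 and Ankrd1 by 1.19 ± 0.17, and Ces1d fell by 1.41 ± 0.25 on the log2 scale. The sixth call was the second Fhl1 probe set, with 1.51 ± 0.23. Nppa kept its call in each run, while a fit of the female arrays alone ended those of Acta1, Ankrd1 and Dohh (adjusted p = 0.243, 0.169 and 0.348). Ces1d lost its call whichever of the 6 female arrays was left out (adjusted p up to 0.249), without the filter (0.217), and with the replicate number as a block in females alone (0.0727) or in both sexes (0.278). It also lost it with the lower floor, where its log2 change was -2.02 (adjusted p = 0.440), and with the offset, where it was -1.13 (adjusted p = 0.0623). Dohh lost its call as well with the lower floor (adjusted p = 0.999), the offset (0.107), the block in both sexes (0.197), no filter (0.0561) and without female sham 1 (0.0513), and Ankrd1 without female sham 1 or female TAC 3 (adjusted p up to 0.0513). At an unadjusted p under 0.05 there were 120 higher and 222 lower probe sets, 342 in all where 373 would be expected by chance. The median log2 change over all tested probe sets was -0.04. Of 7453 probe sets, limma called 6, of which 5 were higher and 1 was lower, and 3 with the replicate number as a block in both sexes. The count was 2 without female sham 1 and 3 without female TAC 3. Camera called hypertrophy stress and matrix genes higher, with adjusted p of 5.36e-13 and 1.24e-10. It called fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle and calcium handling genes lower, with adjusted p of 1.50e-09, 5.17e-07, 0.00162 and 0.000420. Of these, the hypertrophy stress call held with an estimated correlation (adjusted p = 0.0488), and the others had an adjusted p of 0.123 or 0.536.

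The effect of TAC in males compared 3 TAC with 6 sham hearts. Acta1 rose by 2.22 ± 0.19, Nppa by 2.76 ± 0.29, Dohh by 1.60 ± 0.19, Postn by 1.39 ± 0.25 and Ankrd1 by 1.01 ± 0.15. Acta1 and Nppa kept their calls in each run. Postn lost its call in 8 of the 9 runs without 1 male array (adjusted p up to 0.373), with the lower floor (0.111), the offset (0.0929), no filter (0.278) and the replicate block (0.288). Dohh was below the floor on 4 of the 6 male sham arrays, so the floor limits its value: with the lower floor its log2 change was 2.27, without a call (adjusted p = 0.172). Dohh also lost its call with the replicate block (adjusted p = 0.281), and Ankrd1 without male TAC 5 and with that block (0.0919 and 0.0515). limma called 10 probe sets, all higher, which stood for 8 genes and 2 probe sets without a single symbol. At an unadjusted p under 0.05 there were 222 higher and 240 lower, 462 in all against the 373 expected. Camera called hypertrophy stress and matrix genes higher (adjusted p = 1.42e-14 and 1.70e-09), as well as fibroblast markers (0.0210), antioxidant genes (0.0227) and atrial markers (0.00169). Fatty acid oxidation, oxidative phosphorylation and tricarboxylic acid cycle genes were called lower (adjusted p = 0.00268, 2.21e-06 and 0.00457). The hypertrophy stress call held with an estimated correlation (adjusted p = 0.0327), while the others had adjusted p of 0.214 to 0.633. The number of called probe sets was 3 without male TAC 5, between 4 and 6 without any of the male sham arrays or male TAC 4, and 9 without male TAC 6.

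The difference of the TAC effect between the sexes was tested directly as an interaction. No probe set was called by limma, and 191 had an unadjusted p under 0.05 where 373 would be expected by chance. The smallest p values belonged to Wbp2, with a difference of -0.99 ± 0.20 (female minus male), 1110004F10Rik, with 0.79 ± 0.20, and Ybx2, with -1.06 ± 0.30 (adjusted p = 1.00 for each). No gene list was called, and the smallest adjusted p was that of fatty acid oxidation genes, at 0.0672. Without the filter on dim probe sets, this list and that of calcium handling and ion channel genes were called at the preset correlation (adjusted p = 0.0425 and 0.0468), and with the filter and an estimated correlation both had an adjusted p of 0.945. Over all tested probe sets, the changes in females and males had a Pearson r of 0.289 and a Spearman rho of 0.216 across genes, which are not independent replicates, and 58.1% had the same sign. The 6 female calls all had the same sign in males, as 9 of the 10 male calls did in females. Of the 6 female calls and 10 male calls 5 were shared, where 0.00805 would be expected of independent calls. Both contrasts use the same estimate of spread for each probe set. The calls are therefore not independent, and this expectation can be too low.

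**Figure D3:**
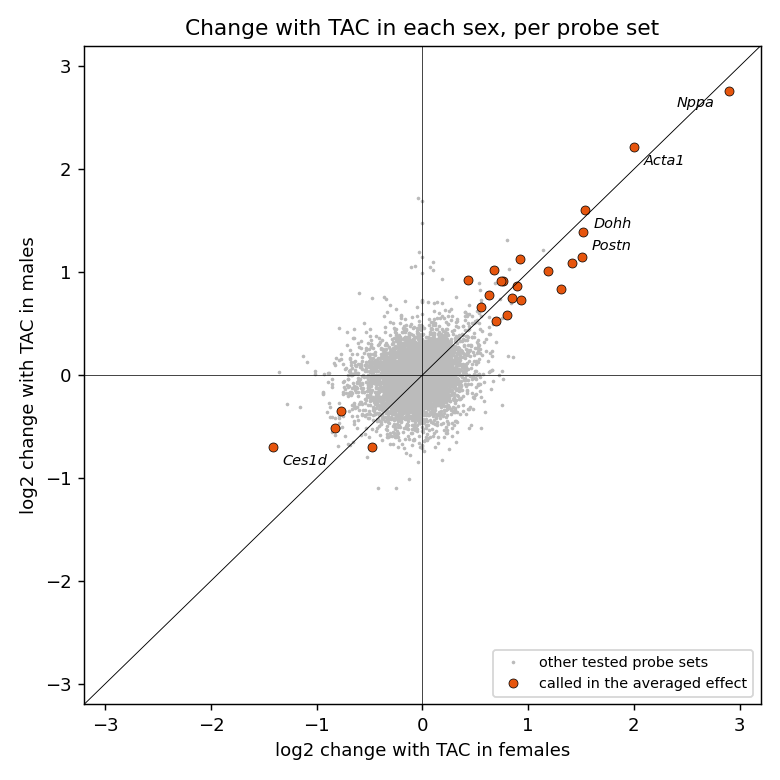
Log2 change with TAC in females (x axis) against that in males (y axis) for the 7453 tested probe sets, with the 24 called in the averaged effect in orange and a line of equal change. Nppa lies at 2.90 and 2.76.

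Female and male sham hearts were compared next. No probe set passed in limma, with 351 at an unadjusted p under 0.05 and 373 expected by chance. The smallest p values were those of Ddx3x, an X-linked helicase gene, with 0.88 ± 0.15 (female minus male, adjusted p = 0.151, called in 3 of 11 alternatives), Trav9d-3, with 1.10 ± 0.22 (adjusted p = 0.434), and Xist, which was at least 1.65-fold higher in females (adjusted p = 0.483). The 3 alternatives that called Ddx3x include the additive model, which takes the sex difference over sham and TAC hearts together. Camera called sex chromosome genes higher in females (adjusted p = 6.02e-10), with all 4 tested members higher, and this held with an estimated correlation (adjusted p = 0.00766). The tested members were the X-linked genes Xist, Ddx3x, Kdm6a and Eif2s3x. No Y-linked member was tested, so this call serves as a check of the labels. Fibroblast markers were called higher in females with a median of 0.18 (adjusted p = 0.00798) and immediate early genes lower with a median of -0.13 (adjusted p = 0.00717). Both were lost with an estimated correlation (adjusted p = 0.563 and 0.409). Among the fibroblast markers 4 were called when adjusted over the list alone: Mgp, Thy1, Pdgfra and Gsn, with differences of 1.11 ± 0.32, 0.42 ± 0.15, 0.58 ± 0.14 and 0.53 ± 0.17.

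Between female and male TAC hearts no probe set was called by limma, with 314 at an unadjusted p under 0.05. The smallest p values were those of Tgfb1, with -0.76 ± 0.16 (female minus male), Smoc2, with 0.81 ± 0.17, and Ddx3x, with 0.77 ± 0.17 (adjusted p = 0.569 for each). Sex chromosome genes, again X-linked members only, were called higher in females (adjusted p = 4.67e-06), and this held with an estimated correlation (adjusted p = 0.0486). Fatty acid oxidation genes were called lower in females, with 17 of 25 lower and a median of -0.10 (adjusted p = 0.0222), which was lost with an estimated correlation (adjusted p = 0.980).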

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

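The tests of the beta-actin signal against other Actb probe sets and against Gapdh, of Nppa against atrial genes, and of the range of the cell type lists were chosen after the results were seen, the last of them after several groupings of those lists and intensity limits had been looked at.

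In the male sham group, the only one with enough arrays for the check, 12 of 89 items had 1 array far from the other 5 on the floored log2 scale, where chance alone gives about 1 in 20. The floor contributes, since 8 of the 12 had 3 or more of the 6 arrays at it. On the deposited intensities 7 genes would have been singled out, 4 of them on both scales. The highest array was male sham 4 for Dohh (32.7) and Ninj1 (27.9), and male sham 8 for Postn (35.3), Txnrd1 (21.3), Cd74 (302) and Kdm6a (23.5). It was male sham 9 for Fhl1 (248), Pfkp (36.4) and Pgam1 (30.2), male sham 5 for Hspa1a (46.9) and male sham 6 for Nqo1 (23.5). Eif2s3x was lowest in male sham 5, at 55.6.

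Among 23 mouse control probe sets, which no comparison used, 2 were higher with TAC by limma with adjustment over the controls. The beta-actin 5-prime set rose by 0.74 ± 0.13 (adjusted p = 0.000876) and the set of the murine B1 repeat by 0.62 ± 0.13 (adjusted p = 0.00232). For the beta-actin set, more beta-actin RNA is argued against as the whole cause, because it rose by 0.588 more than the mean of the other 4 Actb sets (exact permutation p = 0.000595, the smallest the 1680 arrangements can give), although 1 of these, the 3-prime set, rose by 0.41 ± 0.20 (exact permutation p = 0.0327). Better kept 5-prime ends remain open: the 5-prime to 3-prime ratio rose by 0.257 more for beta-actin than for Gapdh, with an exact permutation p of 0.0881. Binding of skeletal alpha-actin RNA, which rose with TAC, remains open too, since within groups the excess had a Pearson r of -0.0754 with Acta1 over 15 arrays (permutation p = 0.818) and a Spearman rho of -0.104 (permutation p = 0.767), and r was -0.452 without the 2 arrays farthest in Acta1. A biological change of the actin transcripts was not tested.

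Lower fatty acid oxidation genes were weighed as a pattern. Scaling between arrays is argued against as the whole cause, since the median was -0.243 after quantile normalization (camera adjusted p = 2.22e-10), and so is the single array female TAC 1, without which it was -0.206 (adjusted p = 6.30e-07). These p-values use the preset correlation, under which the call stands, and not the estimated one, under which it is lost. A lower share of cardiomyocyte RNA was left open by the test fixed before its result was seen. In it 11 contractile genes, with a median of -0.04, lay 0.209 above the fatty acid oxidation genes (p = 0.0948 by permutation of genes between the lists). This p treats genes as independent and does not measure the spread between arrays. The 4 contractile genes with a mean intensity under 2000 had a median of -0.06. In the test chosen afterwards, the mean changes of 4 other cell type lists spanned 0.336 (exact permutation p = 0.00714). They ran from -0.22 ± 0.11 for smooth muscle to 0.12 ± 0.09 for fibroblasts. These lists did not change alike, and a change in those cell types themselves stays open. The test compares other cell types with each other, so it cannot decide whether the share of cardiomyocyte RNA fell.

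Nppa is also abundant in atria, so more atrial tissue in TAC samples was weighed. Its rise exceeded the mean change of Myl7 and Myl4 by 3.04 (exact permutation p = 0.000595, the smallest possible). Nppa alone gave the same p, so this p adds no evidence about atrial tissue. The mean of Myl7 and Myl4 changed by -0.21 ± 0.44, which argues against atrial tissue as the whole cause of a rise of that size. The median change of the atrial list, which includes Nppa, was -0.49 in females and 0.45 in males. A response of the ventricle to TAC remains as a hypothesis.

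Other splits of the arrays were compared with the real one. For the averaged effect 1 of 100 splits, the real one, gave as many calls as its 24, and the highest other gave 3. This share lies under 0.05, which argues against a grouping by luck for this count. It does not exclude chance, since 100 of the 1680 possible splits were drawn and the share was not adjusted over the 6 contrasts. The real split parts all 3 female numbers: of the 44 splits that do so the highest other gave 1 call, and of the 56 that part fewer the highest gave 3. For males 2 of 84 splits gave the real 10 or more, a share under 0.05. The margin is narrow and chance cannot be excluded: exchanging male sham 7 with male TAC 6 gave 13, more than the real split. The real count itself ran from 3 to 18 over the alternatives. For females 1 of 10 splits reached the real 6 and the highest other gave 1, which is too few splits for a share under 0.05. Of these, 4 splits part all 3 female numbers, the real one included, and the 6 that part fewer gave 0 calls. Where the real count is 0 every split reaches it, so the splits say nothing about chance for the difference between the sexes (100 of 100, highest other 4), for the sex difference in sham hearts (84 of 84, highest other 3) or for that in TAC hearts (10 of 10, highest other 1, and too few splits).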

How the results depend on the processing

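The block in females alone and leaving out both female TAC 1 and male sham 7 were chosen after seeing the data. For the averaged effect of TAC, with 24 calls, the count was 45 with quantile normalization, 45 with median centring, 68 with array weights, 10 with the floor at the 10th percentile, 13 without a filter on dim probe sets and 8 with the replicate number as a block (23 with the block in females alone). It was 26 without both female TAC 1 and male sham 7. Leaving out 1 array gave 12 to 29: 14 without female sham 1, 2 or 3, 15 without male sham 6 or female TAC 2, and 12 without male TAC 5. In females, with 6 calls, it was 10 with trended and robust eBayes, 36 with array weights, 2 with only the groups compared and 3 with the replicate block (6 with it in females alone), and 2 to 8 without 1 array (2 without female sham 1, 3 without female TAC 3). In males, with 10 calls, it was 18 with median centring, 3 with the lower floor, 6 with an offset, 4 without the filter, 16 with trended and robust eBayes, 5 with 1 probe set per gene and 3 with the replicate block. It was 3 to 9 without 1 array: 3 without male TAC 5, 4 without male sham 5, 6, 7 or 9, 5 without male sham 4, and 6 without male sham 8 or male TAC 4. The male numbers did not pass the pairing check, and the block in females alone changed no named gene or list other than Pik3ca, Ech1 and, in females, Ces1d. The difference between the sexes stayed at 0 calls under each alternative run. In sham hearts the sex difference gave 2 calls without the filter, 1 with trended and robust eBayes and 2 with array weights. The additive model takes the sex difference over sham and TAC hearts together. Its 1 call is therefore a single result and belongs to neither operation alone. Called lists in the averaged effect, 8 with the preset correlation, numbered 1 with an estimated correlation and 5 with fry, and 7 to 9 without 1 array. In females 6 became 1 with either, in males 8 became 1, and the sex difference lists, 3 in sham and 2 in TAC hearts, became 1. Quantile normalization added a call of the extracellular matrix list for the sex difference in TAC hearts (camera adjusted p = 0.0320, preset correlation). The difference between the sexes, with 0 lists, gave 2 without the filter. Over all settings, values of named genes kept their side of the threshold 2496 times, lost a call 141 times and gained one 33 times, and those of lists did so 891, 44 and 5 times. No named gene or list reversed its direction after being called. Without the filter more probe sets are tested, which alone does not explain the calls that Hrc and Eno3 gained there (limma adjusted p = 0.0345 for each). Leaving out arrays leaves fewer samples. The block in both sexes does so too for the male effect, since male sham 7 to 9 have no TAC partner. It also fits more terms to the same arrays, so calls lost with it do not show that pairing is the cause. For the other settings the cause was not tested. Signal near the floor limits dim genes.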

Other observations

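The genes of the next 2 paragraphs were chosen after their values were seen. Nppb, the gene of brain natriuretic peptide, had a log2 change of 1.18 ± 0.29 with TAC but did not pass in limma (adjusted p = 0.125). Its mean intensity was 759 in female sham, 1617 in female TAC, 698 in male sham and 1543 in male TAC hearts. Myh7, the slow myosin heavy chain, had 0.03 ± 0.08 (adjusted p = 0.948) with means from 4551 to 4818 in the 4 groups. Its probe set is one of a gene family and can bind other myosin transcripts, so the value says little about Myh7 itself. Mgp, matrix Gla protein, had 1.05 ± 0.25 (adjusted p = 0.0982, called in 6 of 13 alternatives) and Lum, lumican, 0.57 ± 0.12 (adjusted p = 0.0585).

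Further calls in the averaged effect were Plekho1 with 0.88 ± 0.12, Ndrg4 with 0.61 ± 0.13, Hbegf, a growth factor of the EGF family, with 0.61 ± 0.12, Dynll1 with 0.69 ± 0.14 and Ighm with 0.71 ± 0.11. Ndrg4, Hbegf and Dynll1 passed narrowly in limma (adjusted p = 0.0495 for each). The called Plekho1 set was below the floor on 2 of the 3 female and 5 of the 6 male sham arrays. How these calls depend on the settings or on single arrays was not followed by gene. The other probe sets of Plekho1 had 0.14 ± 0.19 and 0.13 ± 0.15, and that of Ndrg4 had 0.07 ± 0.15, and none of them passed. Ighm is annotated to many probe sets of a gene family, and the others did not pass, so this value is uncertain. The brightest Ighm set had -0.03 ± 0.10, and the sets that did not pass ran from -0.35 ± 0.14 to 0.54 ± 0.18.

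Gene families grouped by name after the data were seen gave no call in camera over 17 families, and the smallest adjusted p was 0.251. The atrial light chain genes Myl7 and Myl4 varied together over the 15 arrays, with a Pearson r of 0.919 (permutation p = 3e-05) and a Spearman rho of 0.911 (permutation p = 5e-05), and r was 0.884 without the 2 arrays farthest in Myl7. Myl7 ranged from 42.2 to 257 in intensity units. The arrays least correlated with the others were female TAC 1, with a mean Spearman correlation of 0.912 and 48.4% of probe sets below the floor, and male sham 7, with 0.918.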
